A study of Homo sapiens with 52 samples.

How the data were processed

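RNA from 52 kidney allograft biopsies, taken 12 months after transplantation, was hybridised to Affymetrix exon arrays, 1 array per biopsy. Per the labels, 15 biopsies showed acute rejection (AR) and 37 did not (non-AR). Per the labels' protocols, RNA was extracted with a column kit, checked by capillary electrophoresis and amplified with 1 of 2 kits, ENCORE or Ovation SPIA, and SPIA served samples of low RNA concentration. The ENCORE set held 6 AR and 23 non-AR biopsies and the SPIA set held 9 AR and 14 non-AR biopsies. The kit, the RNA yield and any difference in who was biopsied in each set cannot be told apart.

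The authors deposited log2 expression values. Per the submitters' processing notes, RMA and Affymetrix Expression Console were used, with versions not given in the sources used here. Whether features were filtered or values were adjusted for the kit before deposit is likewise not given in the sources used here, nor is a genome build, so no coordinates are printed. The table held 16885 features with values from -0.40 to 13.6. Column medians lay between 5.05 and 5.83. No detection call or background level came with the values, so the number of arrays limits the precision and a floor cannot be set. The labels treat the 52 samples as separate biopsies. Whether 1 person gave more than 1 of them is not given in the sources used here, and p-values assume that the biopsies are independent. The highest correlation between 2 arrays was 0.976, and no pair held identical values.

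Features were named through the platform annotation, with symbols updated through Entrez identifiers in a RefSeq gene table of GRCh38.p14. Of the features, 13664 had 1 gene symbol, 2262 had several and 959 had none. Of the single-symbol features, 13640 were matched by Entrez identifier, 22 by symbol, and 2 kept the platform symbol. In 18 cases the symbol changed. Features of XIST, its neighbours and Y-linked genes, 29 in all, were left out of every test and output. For the 191 genes with more than 1 feature, the feature with the highest mean over all samples was used. This left 13463 genes.

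Differences between AR and non-AR were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with group and kit as terms, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The same fit gave the SPIA minus ENCORE difference, and a fit with an interaction term tested whether the AR effect differed between kits. On simulated values for the 13463 genes with 200 genes changed between AR and non-AR, the fit recovered 55% of genes changed by 0.5 on the log2 scale and 95% of those changed by 1. Of its calls, 5.66% were false.

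Before the data were examined, 32 gene lists with 674 entries were fixed, of which 521 entries were measured. They covered leukocyte classes, interferon and antigen presentation, innate sensing, complement, chemokines, nephron segments, endothelium, matrix, metabolism and control genes. Of the 499 distinct measured list genes, 20 stood in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A list score was also formed for each biopsy as the mean z score of the list's genes after the kit mean had been removed. Where arrays were left out of a group test over all samples, the z scores were formed anew. Score differences from such tests are therefore not in the units of those over all arrays. Tests within a kit and correlations kept the scores formed over all arrays. Group differences in scores were tested by permuting group labels within kits 100000 times, two-sided, with adjustment over the 32 lists. The smallest p this can give is 1e-05. Within a kit, all 475020 splits of the ENCORE samples or all 817190 splits of the SPIA samples were enumerated, which makes those tests exact. On simulated scores with a shift of 1 SD between AR and non-AR, 94.0% of 100 shifted scores and 6.0% of as many unshifted scores had p under 0.05. Whether the effect on a score differed between kits was tested with 10000 permutations of residuals. Correlations between scores carry permutation p-values, adjusted over 8 relations. Scores were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

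The rule for named genes was also fixed beforehand. It took the 12 largest differences in each direction among called genes with the same sign in each kit, up to 4 members of each list with the smallest p, the 6 largest kit differences past the threshold in each direction, and the 3 largest interactions in each direction or else the 3 with the smallest p. It added HCK and the 11 genes of the common rejection module whatever their values. HCK and the module gene PSMB9 were not analysed here, since no feature carried their symbol alone.

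The alternatives tried were no kit term, the kit as a random block, each kit alone, leaving out the 33.3% of genes with the lowest mean expression, the mean of a gene's features, quantile normalization over all arrays or within kits, centring on the median, array weights, a weight per kit, an intensity trend with robust variances, a 1.5-fold minimum, thresholds of 0.01 and 0.1, and a residual principal component as covariate. For list scores they were no removal of the kit mean and the median of log2 values. Leaving out 1 array with a narrow range of values (over all samples or within the SPIA set), leaving out that array together with the AR array of next lowest proximal tubule score, and using each array's interquartile range as a covariate were chosen after seeing the data.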

Results

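Expression was measured on exon arrays in 52 biopsies of transplanted kidneys, 15 with acute rejection (AR) and 37 without (non-AR). The series was described as a discovery set for gene signatures of acute rejection. The labels do not give the type or grade of rejection. Values are deposited log2 signals. One AR array amplified with SPIA stood apart, with an interquartile range of 1.25 against a median of 2.02 over all arrays. Its median correlation with the other arrays was 0.565, against 0.852 for the next lowest. The mean interquartile range was 1.88 ± 0.21 (SD, n = 15) on AR and 2.01 ± 0.18 (SD, n = 37) on non-AR arrays. The array with the range of 1.25 is called the narrow array, and it was kept unless stated.

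Most leukocyte list scores were higher, and proximal tubule and distal nephron list scores lower, in AR than in non-AR biopsies. Of 13463 genes, 521 were higher and 891 lower in AR at an adjusted p under 0.05 (limma, kit as a term), 1412 in all, and 3515 had an unadjusted p under 0.05, where 673 are expected by chance. All 1412 had the same sign in ENCORE and in SPIA samples, but they were called on both kits pooled, which favours like signs. This is therefore no replication between kits. At least a 2-fold difference was reached by 66 of them, 50 higher and 16 lower. With the narrow array left out the count was 1227, split into 611 higher and 616 lower, of which 477 and 595 were also called on all arrays in the same direction, and the share of calls that were higher moved from 36.9% to 49.8%. Quantile normalization gave 592 higher and 628 lower within kits, and 598 and 634 over all arrays. ENCORE samples alone gave 171 higher and 12 lower, while SPIA samples alone gave 15 higher and 188 lower, or 56 and 172 with the narrow array left out. Of the 32 gene lists, 22 passed by camera at the preset correlation (18 higher, 4 lower), 6 with an estimated correlation and 21 by fry. When the narrow array was left out 12 passed with an estimated correlation, adding checkpoint, interferon gamma, HLA, macrophage, chemokine and oxidative phosphorylation genes. By permutation 20 list scores passed (16 higher, 4 lower).

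The 12 largest increases included 3 chemokines and 3 T cell markers of the lists, and 4 of the 12 genes stood in no list. CXCL9, a chemokine that draws T cells through CXCR3, was higher by 1.98 on the log2 scale (SE 0.48, adjusted p = 0.00569), or 3.94-fold, with group means of 7.93 ± 1.74 (SD, n = 15) and 6.10 ± 1.53 (SD, n = 37), and lay above the non-AR median of its kit in 13 of 15 AR biopsies. Its relatives CXCL11 and CXCL10 were higher by 1.89 (SE 0.51, adjusted p = 0.0128) and 1.55 (SE 0.43, adjusted p = 0.0147). GPR174, a G protein coupled receptor of lymphocytes, was higher by 1.92 (SE 0.37, adjusted p = 0.00116). The T cell receptor complex chains CD3D, CD3E and CD3G rose by 1.72, 1.57 and 1.42. GBP5, a guanylate binding protein induced by interferon gamma, rose by 1.67, an immunoglobulin lambda variable segment by 1.73, lysozyme (LYZ) by 1.60, the inhibitory receptor BTLA by 1.43 and PLAC8 by 1.41. The adjusted p-values of these 8 genes lay between 0.00117 and 0.0146.

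Of the 12 largest decreases 4 stood in the nephron lists, EGF, PVALB, HAO2 and KNG1, and the others in no list. SPINK1, a serine protease inhibitor, differed by -1.68 (SE 0.54, adjusted p = 0.0353), and the mucin MUC13 by -1.31 (SE 0.45, adjusted p = 0.0486). EGF, the epidermal growth factor made in the distal nephron, differed by -1.27 (SE 0.26, adjusted p = 0.00196) and lay above the non-AR median of its kit in 1 of 15 AR biopsies. LRRC19 differed by -1.06 (SE 0.20, adjusted p = 0.00116) and exceeded that median in 0 of 15. AFM, TMED6, SLC7A13, PVALB, HAO2, UPP2, KNG1 and SLCO4C1 differed by -1.24 to -1.05. SPINK1, MUC13 and the amino acid transporter SLC7A13 no longer passed with the narrow array left out (adjusted p = 0.0802, 0.0906 and 0.0935). Their differences were then -1.32, -1.17 and -1.03. After quantile normalization within kits MUC13 and SLC7A13 did not pass (adjusted p = 0.0543 and 0.0608), and without a kit term SPINK1 and MUC13 did not (adjusted p = 0.0596 and 0.0655).

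**Figure D1:**
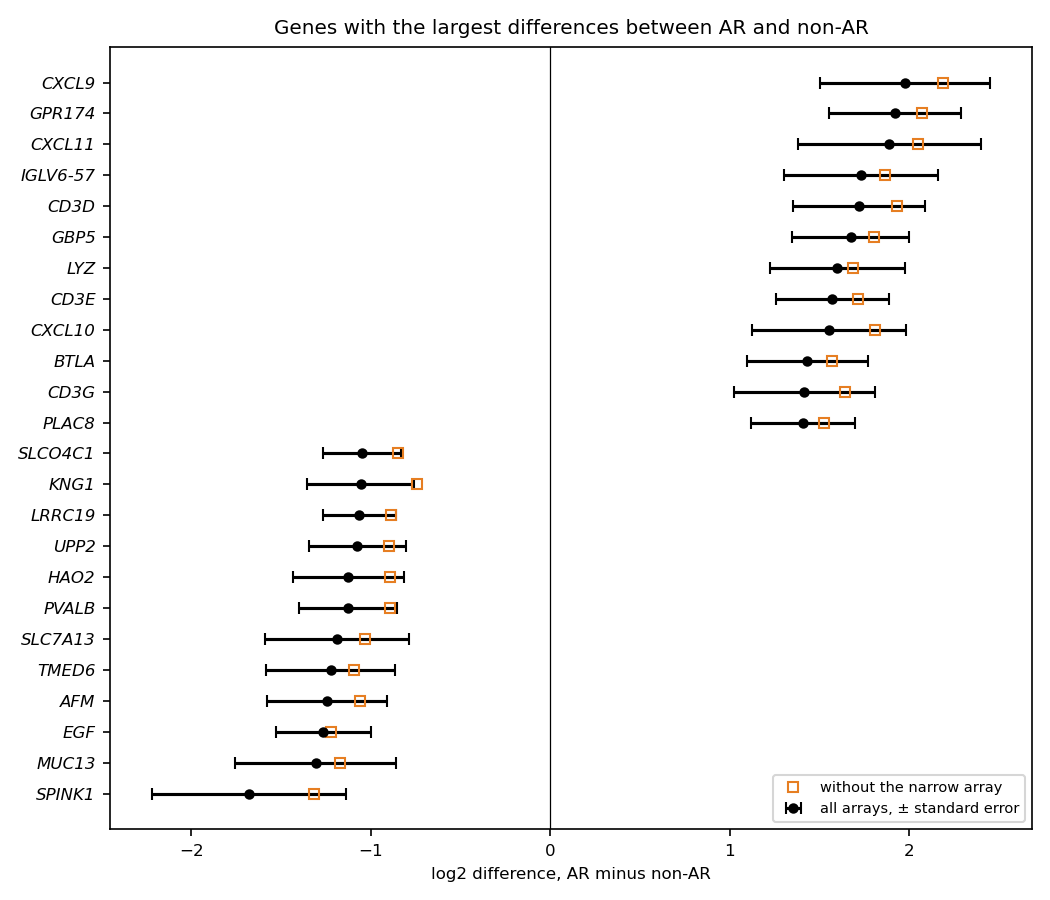
Log2 difference between AR (n = 15) and non-AR (n = 37) biopsies for the 12 genes with the largest positive and the 12 with the largest negative differences past the threshold. Filled points with bars are the limma estimate and its standard error, open squares the estimate without the narrow array. CXCL9 is highest at 1.98 and SPINK1 lowest at -1.68.

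T cell and cytotoxic genes rose. All 19 measured T cell markers rose, over all genes and adjusted over the list alone, those with the smallest p being LCK (0.55, SE 0.10), CD6 (0.39, SE 0.07), SLAMF6 (1.34, SE 0.25) and CD3E. The T cell list score was higher in AR by 1.12 z units (permutation test, adjusted p = 0.00016), with means of 0.80 ± 1.04 (SD, n = 15) and -0.32 ± 0.54 (SD, n = 37), and 12 of 15 AR biopsies lay above the non-AR median. Of 17 cytotoxic and NK cell genes 13 rose, 14 adjusted over the list alone, among them perforin (PRF1, 0.43) and granulysin (GNLY, 0.76), which act in the killing of target cells, with CST7 (0.66) and CTSW (0.79). Their score was higher by 0.92 (permutation test, adjusted p = 0.00016). Of 11 checkpoint and regulatory genes 5 rose and 1 fell, the same counts adjusted over the list alone, and the score was higher by 0.57 (permutation test, adjusted p = 0.000448). TNFRSF9 (0.50), TIGIT (0.45), CD274 (0.61) and CTLA4 (0.44) were among those that rose, CTLA4 losing its call after quantile normalization within kits (adjusted p = 0.0541). CTLA4 lay above the non-AR median of its kit in 8 of 15 AR biopsies. It differed by 0.84 in ENCORE and 0.10 in SPIA samples, and the interaction did not pass (limma, adjusted p = 0.59). The other members past the threshold, chosen after their values were seen, were LAG3 (0.23) and HAVCR2 (-0.56), whose adjusted p was 0.0771 with the narrow array left out. The list calls of T cells and cytotoxic cells held with an estimated correlation (adjusted p = 0.0377 for each), and that of checkpoint genes did not (adjusted p = 0.0522 with an estimated correlation, and 0.605 without the dimmest genes).

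Interferon gamma induced genes rose, and calls for type I interferon stimulated genes depended on the setting. Of 17 interferon gamma induced genes 13 rose, 14 adjusted over the list alone, including the transcription factors IRF8 (0.97, SE 0.18) and IRF1 (0.70, SE 0.14) and the immunoproteasome subunit PSMB10 (0.57, SE 0.12). The list score was higher by 0.94 (permutation test, adjusted p = 0.000249), and the list call had an adjusted p of 0.0518 with an estimated correlation. Of 20 type I interferon stimulated genes 0 passed over all arrays, also adjusted over the list alone, and 2 (OAS2 and EPSTI1, the latter named after its value was seen) with the narrow array left out. Their score differed by 0.20 (permutation test, adjusted p = 0.419), or 0.33 with the narrow array left out (adjusted p = 0.175), and 14 of 15 AR biopsies lay above the non-AR median. At the preset correlation the list did not pass by camera (adjusted p = 0.057). It did without that array (0.0126), in ENCORE samples (5.5e-05), without the dimmest genes (0.00898) and with the interquartile range as a covariate (0.00158). With an estimated correlation camera gave it an adjusted p of 0.593 over all arrays, 0.489 without that array and 0.266 in ENCORE samples. Single values were 0.61 for OAS2 (adjusted p = 0.0514; 0.0334 with the narrow array left out and 0.0367 after quantile normalization within kits) and -0.60 for IFIT1 (adjusted p = 0.0624). Among 9 HLA class I and class II genes all had a positive difference, 1 rose over all genes (HLA-DOA, 0.49) and 3 adjusted over the list alone, with HLA-E (0.59) and HLA-F (0.44). The HLA score was higher by 0.65 (permutation test, adjusted p = 0.0195; list call adjusted p = 0.208 with an estimated correlation). The score call was lost when the kit mean was not removed (adjusted p = 0.0751) or the median of log2 values was used (adjusted p = 0.0871), while with the narrow array left out the score difference was 1.01 (adjusted p = 0.000262) and 7 of the 9 genes rose.

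Of the common rejection module, a set of genes reported as raised across transplanted organs, 9 of 10 measured members rose, also adjusted over the list alone. CXCL9, CXCL10, TAP1 (0.71), NKG7 (0.69), LCK, INPP5D (0.48), ISG20 (0.42), CD6 and RUNX3 (0.33) passed, and BASP1 differed by 0.12 (adjusted p = 0.441). Its score was higher by 1.04 (permutation test, adjusted p = 0.00016), and its list call held with an estimated correlation (adjusted p = 0.0377). Of these genes 6 also stand in the T cell, cytotoxic or interferon gamma lists.

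Most macrophage and dendritic cell markers rose, and 1 of 11 neutrophil markers did. Of 25 macrophage and monocyte markers 15 rose, 22 adjusted over the list alone, with ITGAX at 0.49 (SE 0.09), ITGB2 at 0.65 (SE 0.13), LYZ at 1.60 and LILRB1 at 0.53 (SE 0.13). The macrophage score was higher by 0.85 (permutation test, adjusted p = 0.000611), and its list call had an adjusted p of 0.0634 with an estimated correlation. With the narrow array left out 22 of the 25 rose. Of 13 dendritic cell markers 9 rose, 11 adjusted over the list alone, among them XCR1 (0.46) and CLEC9A (0.64), which mark cross-presenting cells, and CCR7 (0.79). CLEC10A was higher by 0.55. The dendritic cell score was higher by 0.86 (permutation test, adjusted p = 0.000192), and its list call held with an estimated correlation (adjusted p = 0.0377). The neutrophil marker that rose was FPR1 (0.51), also adjusted over the list alone. The neutrophil score was higher by 0.48 (permutation test, adjusted p = 0.00629; list call adjusted p = 0.119 with an estimated correlation and 0.241 without the dimmest genes).

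The series title names innate immune pathways. Of 30 innate sensing and Toll-like receptor pathway genes 10 rose and 0 fell, 12 rising adjusted over the list alone. They included the cytokine IL1B (0.60, SE 0.13), the DNA sensor AIM2 (1.02, SE 0.24) and the receptors TLR7 (0.78, SE 0.20) and TLR6 (0.93, SE 0.24; adjusted p = 0.0667 without a kit term). The score was higher by 0.53 (permutation test, adjusted p = 0.00458), and the list call had an adjusted p of 0.119 with an estimated correlation. Of 15 complement genes 3 rose and 1 fell, 9 and 1 adjusted over the list alone, and 6 and 0 over all genes with the narrow array left out. CFP (0.36), C1QC (0.72) and C1QB (0.60) rose, and complement factor I (CFI) differed by -0.72, which did not pass with that array left out (-0.48, adjusted p = 0.0614), after quantile normalization within kits (0.0673) or without a kit term (0.0575). The complement score was higher by 0.56 (permutation test, adjusted p = 0.0133; list call adjusted p = 0.160 with an estimated correlation). Of 22 chemokines and receptors 12 rose, 14 adjusted over the list alone, with CCL5 at 1.31 (SE 0.21, adjusted p = 0.000373), CCR7 and CXCR3 (0.38). Their score was higher by 0.79 (permutation test, adjusted p = 0.000249; list call adjusted p = 0.0518 with an estimated correlation).

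B cell and plasma cell markers were higher in AR. Of 18 B cell markers 10 rose, 14 adjusted over the list alone, including CD72 (0.68), CD37 (0.87), CD22 (0.52) and CD79A (1.01). Of 13 plasma cell markers 9 rose, 12 adjusted over the list alone, including SLAMF7 (1.38), IRF4 (0.92), CD38 (0.91) and PIM2 (0.52). The scores were higher by 0.79 for B cells (permutation test, adjusted p = 0.00016) and 0.90 for plasma cells (permutation test, adjusted p = 0.000249), and both list calls held with an estimated correlation (adjusted p = 0.0377 and 0.0453). The plasma cell score difference was 1.56 in ENCORE samples (exact test, adjusted p = 0.000876) and 0.41 in SPIA samples (exact test, adjusted p = 0.172). The test of that difference between kits did not pass (permutation test, adjusted p = 0.0992).

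Nephron and mitochondrial list scores were lower in AR. Of 26 proximal tubule genes 10 fell and 0 rose, 23 falling adjusted over the list alone, and 6 fell over all genes with the narrow array left out. The phosphate transporter family member SLC17A1 differed by -0.94 (SE 0.25), the peroxisomal oxidase HAO2 by -1.12 (SE 0.31), the acyltransferase GLYAT by -0.98 (SE 0.28) and the organic cation transporter SLC22A2 by -0.57 (SE 0.16), the last not passing after quantile normalization within kits (adjusted p = 0.0573). The proximal tubule score differed by -0.74 (permutation test, adjusted p = 0.00744), with means of -0.53 ± 1.37 (SD, n = 15) and 0.21 ± 0.51 (SD, n = 37). Of 20 loop of Henle and distal nephron genes 4 fell, namely EGF, PVALB (-1.13), the proton pump subunit ATP6V0D2 (-0.95) and KNG1 (-1.06), and 9 fell adjusted over the list alone. Their score differed by -0.64 (permutation test, adjusted p = 0.00125). The list called oxidative phosphorylation here also holds other mitochondrial genes and the coactivator PPARGC1A. Of its 17 measured genes 6 fell, 8 adjusted over the list alone, among them UQCRC2 (-0.50), ETFDH (-0.79), PPARGC1A (-0.91) and NDUFB5 (-0.62). In 14 of 15 AR biopsies its score did not exceed the non-AR median. The score differed by -0.69 (permutation test, adjusted p = 0.000249). Of 17 fatty acid oxidation genes 5 fell, 8 adjusted over the list alone, including ACADM (-0.88), ACAA2 (-0.79), HADH (-0.62), EHHADH (-0.91) and, named after its value was seen, HADHB (-0.49; adjusted p = 0.0756 with the narrow array left out), and their score differed by -0.64 (permutation test, adjusted p = 0.0108). The non-AR median was exceeded by 6 of 15 AR biopsies for the proximal tubule score. It was exceeded by 5 for the fatty acid oxidation score and by 1 for the distal nephron score.

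With an estimated correlation the list calls of these 4 groups were lost, at adjusted p of 0.209 for proximal tubule, 0.143 for distal nephron, 0.0534 for oxidative phosphorylation and 0.209 for fatty acid oxidation genes. With the narrow array left out, all 4 scores passed, the largest adjusted p being 0.0252. Without it and the AR array of next lowest proximal tubule score, both amplified with SPIA, the proximal tubule and fatty acid oxidation scores no longer passed (permutation test, adjusted p = 0.0603 for each), whereas distal nephron (0.00396) and oxidative phosphorylation (0.0008) scores did. Over the other alternatives the adjusted p lay between 0.00638 and 0.0158 for proximal tubule and between 0.0122 and 0.0252 for fatty acid oxidation scores. In ENCORE samples alone the proximal tubule score differed by -0.32 (exact test, adjusted p = 0.347) and in SPIA samples by -1.17 (exact test, adjusted p = 0.0374), or -0.76 with the narrow array left out (adjusted p = 0.0347). The test of the difference between kits gave an adjusted p of 0.414 by permutation (-0.85), or 0.743 with that array left out (-0.53).

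Within kits, the 16 list scores that were higher and the 4 that were lower over all samples kept their direction. Their choice on the pooled samples favours this. The 16 differed by 0.46 to 1.56 in ENCORE samples, where 13 passed, and by 0.28 to 0.86 in SPIA samples, where 3 passed (exact tests, adjusted over 32 lists). The 3 were the common rejection module, cytotoxic and B cell scores. In SPIA samples the T cell (0.86, adjusted p = 0.0693), macrophage (0.80, 0.0753) and interferon gamma scores (0.60, 0.122) did not pass. With the narrow array left out they did (adjusted p = 0.0244, 0.01 and 0.0244). The SPIA differences of the 16 were 0.46 to 1.04 with the narrow array left out, where 11 passed, and that of HLA genes went from 0.28, the lowest, to 0.70. The 4 lower scores differed by -0.47 to -0.23 in ENCORE samples, where 0 passed, and by -1.17 to -0.93 in SPIA samples, or -0.84 to -0.60 with the narrow array left out, where all 4 passed in either case. Of these the distal nephron score went from -0.93 to -0.60. No score passed the test of a difference between the kits, the smallest adjusted p being that of the plasma cell score.

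**Figure D2:**
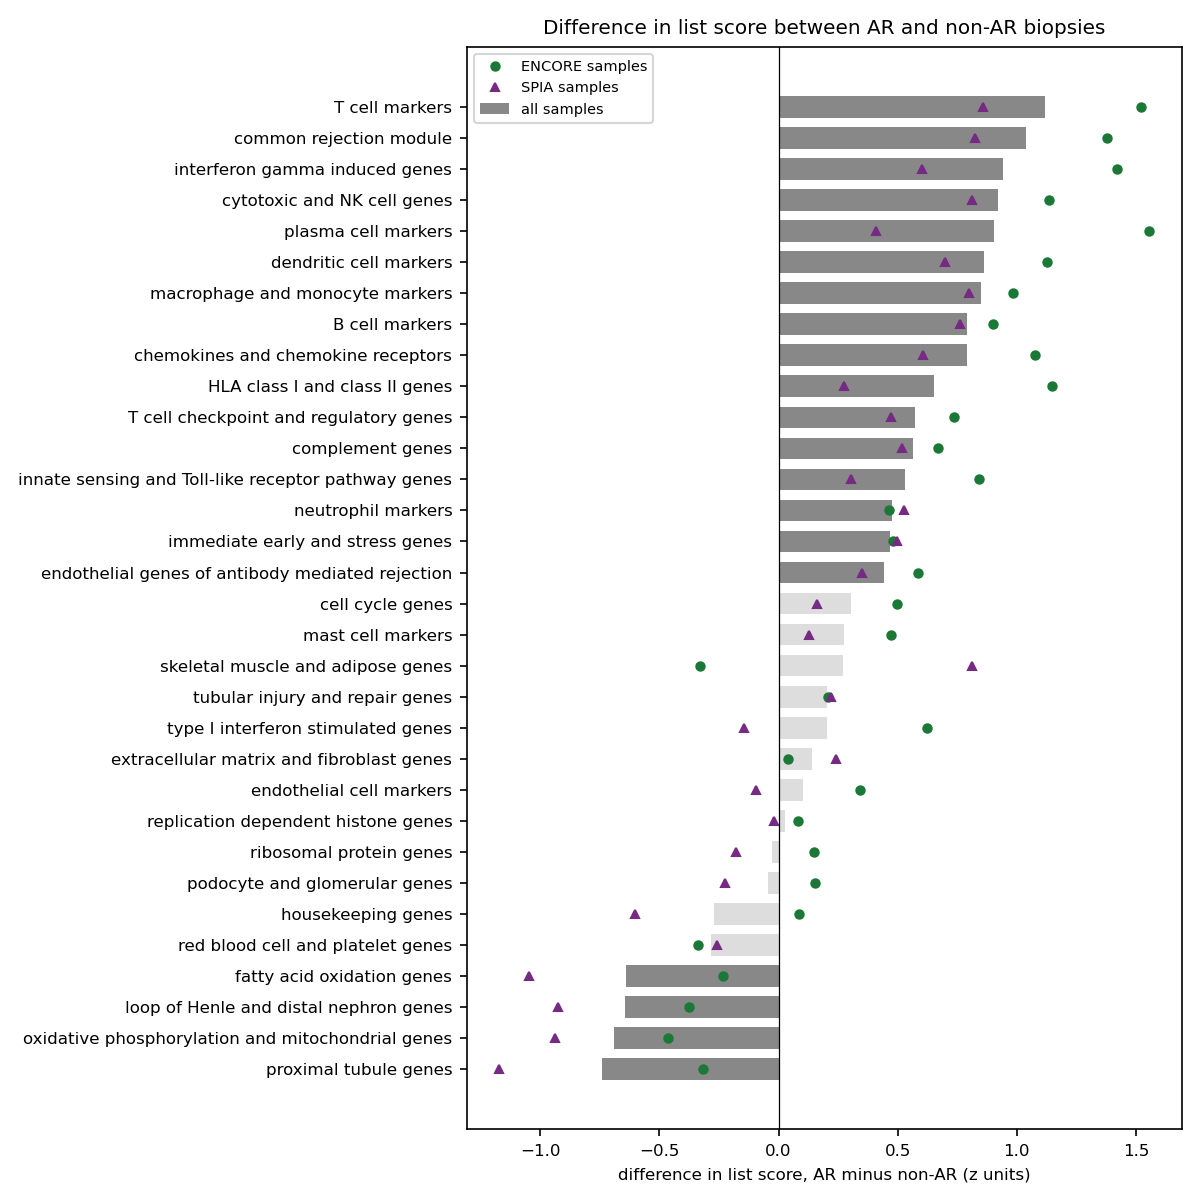
Difference in list score between AR and non-AR biopsies, in z units, for the 32 gene lists. Bars are all 52 samples, dark where the adjusted permutation p is under 0.05, circles the ENCORE samples and triangles the SPIA samples. The T cell list is highest at 1.12 and the proximal tubule list lowest at -0.74.

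In other kidney compartments few genes passed, and several values moved with the narrow array. Of 12 podocyte and glomerular genes SYNPO rose (0.20) and MME fell (-0.86), also adjusted over the list alone, and the score differed by -0.05 (permutation test, adjusted p = 0.885), or 0.09 with the narrow array left out (adjusted p = 0.673), where MME was at -0.55. Neither passed after quantile normalization within kits (adjusted p = 0.0643 and 0.0717). MME, a membrane peptidase, is also made by proximal tubule. Of 16 endothelial markers VWF alone rose (0.38), also adjusted over the list alone (score difference 0.10, permutation test, adjusted p = 0.645), and 2 rose with the narrow array left out (score difference 0.24, adjusted p = 0.221). Of 15 endothelial genes linked to antibody mediated rejection 3 rose, VWF, THBD (0.26; adjusted p = 0.0507 without a kit term) and ACKR1 (0.30), the same number adjusted over the list alone (score difference 0.44, permutation test, adjusted p = 0.0321, or 0.061 with the median of log2 values; list call adjusted p = 0.209 with an estimated correlation), and 6 rose with the narrow array left out. Of 24 tubular injury and repair genes CD44 rose (0.58), with an adjusted p of 0.138 without a kit term. Adjusted over the list alone 0 passed. SPP1 was at -0.61 (adjusted p = 0.0638), or -0.35 with the narrow array left out (adjusted p = 0.0771). VIM passed after quantile normalization within kits (adjusted p = 0.0113). The list call of tubular injury genes had an adjusted p of 0.593 with an estimated correlation, and their score differed by 0.21 (permutation test, adjusted p = 0.417). Of them 2 rose with the narrow array left out, where the score difference was 0.37 (adjusted p = 0.0864). Of 25 matrix and fibroblast genes 0 passed under either adjustment, with TIMP1 passing after quantile normalization within kits (adjusted p = 0.047; score difference 0.14, permutation test, adjusted p = 0.642, or 0.23, adjusted p = 0.41, with the narrow array left out).

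**Figure D3:**
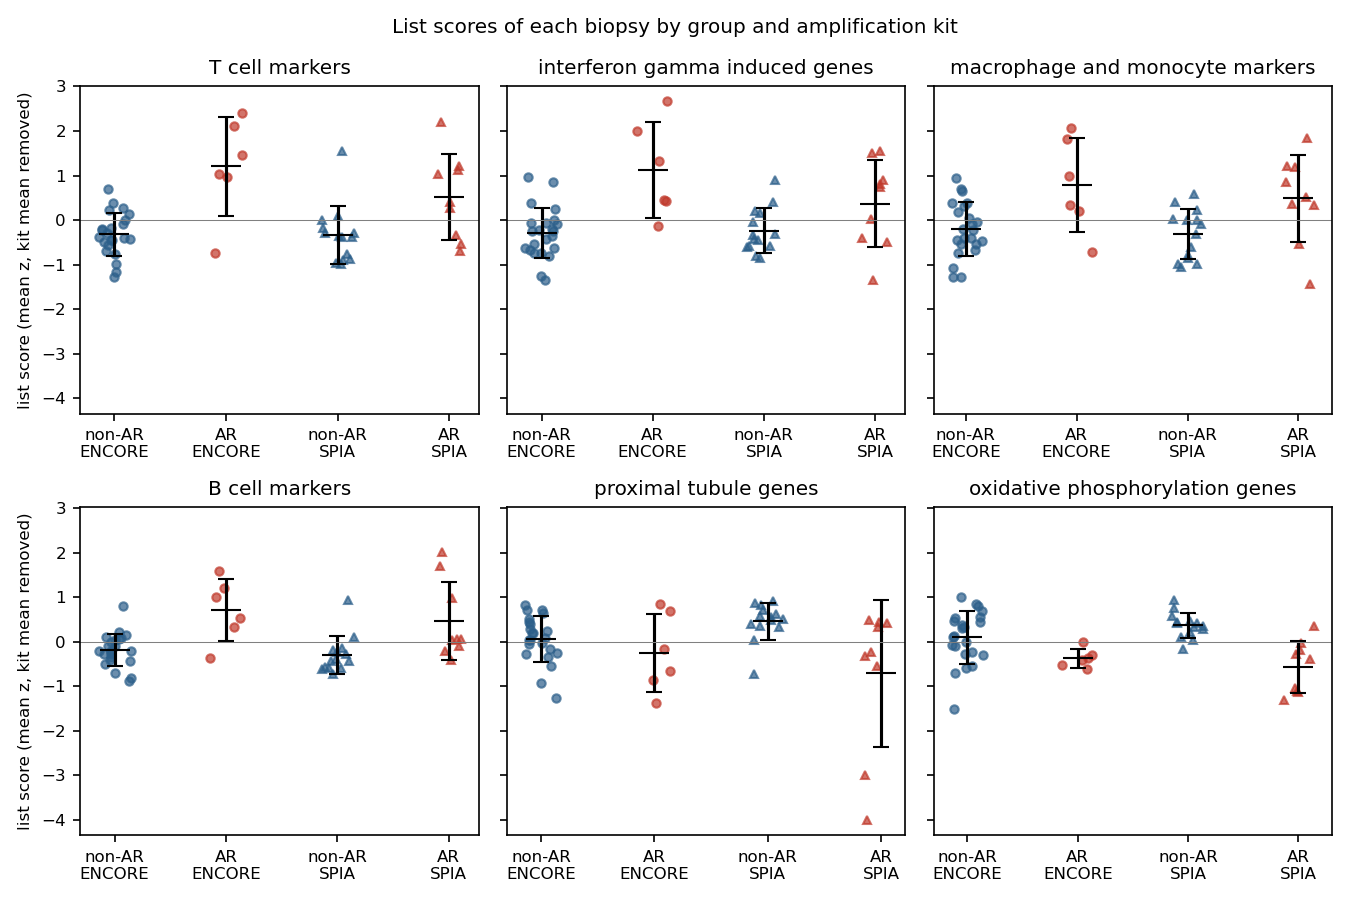
List scores of each biopsy, in mean z units after the kit mean was removed, for 6 lists. Points are biopsies (AR red, non-AR blue), split by ENCORE (circles) and SPIA (triangles), with mean and SD bars. The T cell score averages 0.80 in AR and -0.32 in non-AR, and 2 AR arrays of the SPIA set have far lower proximal tubule scores than the others.

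The amplification kits were compared at fixed group as a technical contrast. No gene passed between SPIA and ENCORE (limma, 0 of 13463, smallest adjusted p = 0.103), and 1068 had an unadjusted p under 0.05. With the narrow array left out 21 passed. By camera at the preset correlation 18 lists, among them T cell and macrophage markers, were lower in SPIA samples, and 0 with an estimated correlation or with fry. The lowest adjusted p with an estimated correlation was 0.127. For the difference of the AR effect between kits, 0 genes passed (limma, smallest adjusted p = 0.59) and 965 had an unadjusted p under 0.05. The genes with the smallest p in each direction were HJV (-0.53 in ENCORE and 0.50 in SPIA samples), LY6G6E (-0.28 and 0.49) and FER1L6-AS2 (-0.20 and 0.37), and in the other direction SYNRG (0.62 and -0.41), TENT5C (1.24 and -0.25) and TNFRSF17 (2.34 and 0.30), all at an adjusted p of 0.59. By camera at the preset correlation 9 lists passed for that difference, the smallest p being that of muscle and adipose genes (median 2.53, adjusted p = 2.47e-11), and 0 with an estimated correlation (0.268 for that list). Across genes, which are not independent replicates, AR effects in the kits correlated with r = 0.399.

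Biopsies with more T cell transcripts had fewer proximal tubule transcripts. Over 52 biopsies the scores had Pearson's r = -0.43 (permutation p = 0.0026, adjusted p = 0.0104) and Spearman's rho = -0.49 (permutation p = 0.00043, adjusted p = 0.00115), in a family of 8 relations. Leaving out the 2 samples farthest from the median T cell score gave r = -0.24 (permutation p = 0.0902). With the narrow array kept, the pooled Pearson's r thus depends on them. Within kits r was -0.52 in ENCORE (adjusted p = 0.00989) and -0.41 in SPIA samples (adjusted p = 0.183), where rho was -0.43 and -0.65. In non-AR biopsies r was -0.45 (adjusted p = 0.0227) and rho -0.43, and in AR biopsies r was -0.20 (adjusted p = 0.751) and rho -0.55 (adjusted p = 0.147). With the narrow array left out r was -0.64, and -0.50 (permutation p = 0.00038) when the 2 farthest of those samples were left out. Without that array the relation therefore did not rest on the 2 farthest samples. For the cytotoxic score against the proximal tubule score, r over all biopsies was -0.40 (permutation test, adjusted p = 0.0174). The macrophage (r = -0.29, adjusted p = 0.0577) and interferon gamma scores (r = -0.25, adjusted p = 0.0869) did not pass by Pearson's r. Their rho was -0.45 and -0.34 (adjusted p = 0.00176 and 0.0176). With the narrow array left out their r was -0.59 and -0.51, and both passed.

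**Figure D4:**
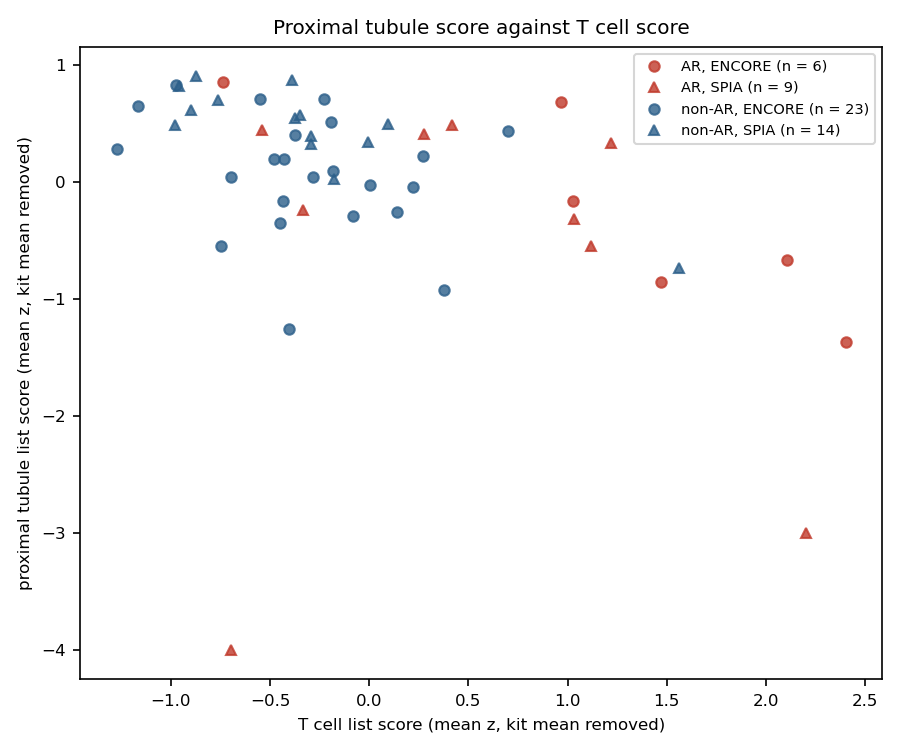
Proximal tubule list score against T cell list score, both in mean z units after the kit mean was removed, with 1 point per biopsy by group and kit. Over all 52 biopsies Pearson's r is -0.43, and the narrow array is the lowest point.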

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

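The tests of explanations in this part, redrawn groupings included, were chosen after the results had been seen. Features outside the gene tests also differed between AR and non-AR. Of 2240 features with several gene symbols 196 passed an adjusted p of 0.05 (limma), 71 higher and 125 lower in AR. Of 959 features with no symbol 92 passed, 36 higher and 56 lower. These are 8.75% and 9.59%, against 10.2% of features with 1 symbol.

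The count of AR genes was not reached by other groupings. With labels redrawn within kits, 1 of 100 splits, the real one, gave as many as 1412 genes. The highest of the others was 5. Chance is therefore unlikely to account for that count, as far as 100 splits can show and if the biopsies are independent.

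More genes were lower than higher in AR, 36.9% of calls being higher. When the narrow array was left out the share was 49.8%. With array quality weights, where that array had the lowest weight (0.0798), the share was 38.5% (692 higher and 1106 lower). Quantile normalization within kits, with that array kept, gave 48.5%. It gives all arrays of a kit the same range, so it cannot separate that array from a general narrowing. Since the share moved when that array was left out but little when it was weighted down, whether it sets the imbalance in the pooled set is not settled. The narrow array cannot be the whole account within SPIA samples, where 24.6% of calls were higher after it was left out. With each array's interquartile range as a covariate the share was 74.7%, but the range itself moved with the group (1.88 ± 0.21 in AR and 2.01 ± 0.18 in non-AR), and loss of bright tubular transcripts would narrow it, so a general narrowing and a biological decrease cannot be told apart here.

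Tubule and mitochondrial scores were lower in AR. The narrow array alone is argued against, since without it the largest adjusted p of the 4 scores was 0.0252. With it and the AR array of next lowest proximal tubule score left out, distal nephron and oxidative phosphorylation scores still passed (largest adjusted p = 0.00396). Proximal tubule and fatty acid oxidation scores did not (adjusted p = 0.0603, permutation p = 0.0389 and 0.0359). For these, a fall beyond those arrays cannot be told apart from a share of it that rests on them, because the arrays were picked by their scores. The differences went from -0.74 to -0.53 and from -0.64 to -0.49, and the SD among AR biopsies from 1.37 to 0.98 and from 0.99 to 0.71. The z scores were formed anew without those arrays, so these values are not in the same units. The proximal tubule SD among non-AR biopsies, all of them kept, went from 0.51 to 0.72. On the log2 scale the proximal tubule difference was -0.66 over all arrays and -0.47 without the narrow array. Proximal tubule and distal nephron lists lay at or under the 0.24 percentile of random lists matched on mean expression in all 3 settings. They thus fell more than genes of like brightness on these arrays. The random lists treat genes as independent, whereas the estimated correlation within these lists was 0.79 and 0.38. The percentiles therefore cannot decide whether a general fall of bright genes is the cause. For oxidative phosphorylation the percentile was 22.4 over all arrays, 1.82 without the narrow array and 1.19 with the interquartile range as a covariate. For fatty acid oxidation it was 0.84, 4.48 and 9.05. For both lists the settings disagree, and a general fall cannot be told apart. Dilution by leukocyte RNA would lower podocyte and endothelial genes as well, and the 4 lists fell more than these 2. The largest adjusted permutation p of these contrasts was 0.0104 over all arrays and 0.0054 without the narrow array. Without that array and the AR array of next lowest proximal tubule score, the largest unadjusted permutation p was 0.026. On the log2 scale the proximal tubule contrast with podocyte genes then went from -0.56 over all arrays to -0.26. That with endothelial genes went from -0.68 to -0.36 (permutation p = 0.0204). The contrasts were not matched on mean expression, and random lists as bright as the proximal tubule list had a median of -0.29 over all arrays. They therefore cannot decide on dilution. Rejection itself and the region of kidney sampled also stay open and untested.

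No gene was called between the kits. Removal of each gene's kit mean before deposit is argued against: the spread over genes of the kit difference had an SD of 0.149, at the 80th percentile of 100 random kit splits (lowest 2.5% at 0.102), where removal at fixed group would leave an SD of 0.0494. Other adjustments for the kit, and kits that give like values, stay open and untested. The kit count and the interaction count were both 0, which 100 of 100 splits reach whatever the data, so the redrawn groupings say nothing about them (highest other counts of 0 and 1).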

How the results depend on the processing

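The tests that leave out the narrow array, alone, with another or within SPIA samples, the interquartile range covariate and the redrawn groupings were chosen after the results had been seen. The AR gene count (1412) stayed within 1.5 times under no kit term, the random block, the mean of features, both quantile normalizations, centring, array or kit weights and the trend, between 1220 and 1798. It was 183 in ENCORE samples (171 higher, 12 lower), 203 in SPIA samples (15 higher, 188 lower) and 228 in SPIA samples without the narrow array (56 higher, 172 lower), with fewer samples in each. A residual principal component as covariate gave 2927 (852 higher, 2075 lower) and the interquartile range 830 (210 lower); the cause was not tested. A 1.5-fold minimum gave 507 (172 higher, 335 lower), a threshold of 0.01 gave 429 (221 and 208) and one of 0.1 gave 2228 (799 and 1429). Without the dimmest 33.3% of genes 246 were higher and 857 lower (22.3% higher); the cause was not tested.

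The kit count of 0 became 18 after quantile normalization, 4 after centring, 14 in non-AR samples and 21 without the narrow array; the cause was not tested. It stayed at 0 without the dimmest genes, and the interaction count was 0 under its 3 alternatives. With an estimated correlation, list calls went from 22 to 6 for AR (12 without the narrow array) and from 18 to 0 for the kits. At the preset correlation calls were lost for checkpoint (0.06, adjusted p = 0.605), neutrophil (0.06, adjusted p = 0.241) and cell cycle genes (0.09, adjusted p = 0.163) without the dimmest genes, HLA (adjusted p = 0.0649) and cell cycle genes (0.0721) in SPIA samples, cell cycle genes after quantile normalization within kits (0.0606), and tubular injury genes without a kit term (0.0643) and in ENCORE samples (0.425). Matrix genes were newly called higher in SPIA samples (adjusted p = 0.0154), without the dimmest genes (0.0111) and after quantile normalization within kits (0.0384). Muscle genes gained such a call in SPIA samples and without the dimmest genes (0.00851). Type I interferon genes did in ENCORE samples (5.5e-05) and without the dimmest genes (0.00898). They also did without the narrow array (0.0126) and with the interquartile range covariate (0.00158). With an estimated correlation the calls in SPIA samples did not pass for matrix (adjusted p = 0.607) and muscle genes (0.260). The same held for type I interferon genes in ENCORE samples (0.266) and without the narrow array (0.489). As many AR lists (22) came from 7 of 100 splits, the real one included, the highest other being 24, and as many kit lists (18) from 16 of 100, the highest other being 23, so chance cannot be excluded for either count at the preset correlation. List scores passed for 20 lists, and for 18 to 21 under the alternatives. The T cell and proximal tubule correlation missed the threshold in SPIA (-0.41) and in AR samples (-0.20), with fewer samples. Without the 2 samples farthest on the T cell score r was -0.07 in SPIA samples (permutation p = 0.737). In AR samples, where those 2 included the narrow array, r was then -0.69 (permutation p = 0.00627). Of 144 genes named for the AR difference 133 kept their direction and side of the threshold with the narrow array left out, 131 after quantile normalization within kits, 134 without a kit term, 82 in ENCORE and 55 in SPIA samples. Signs turned in ENCORE samples for KDR (0.0113), TNNC2 (-0.87) and DES (-0.29), none of them called. List medians turned for muscle genes in ENCORE samples (-0.86, adjusted p = 0.00667 by camera, against 1.64 and 5.03e-06 in SPIA samples), and, without a call, for type I interferon (-0.10) and endothelial genes (-0.0137) in SPIA samples, mast cell markers without the dimmest genes (-0.018) and housekeeping genes in ENCORE samples (0.14) and with the interquartile range covariate (0.0445). They also turned without a call for podocyte (0.0689, 0.0449, 0.0882 and 0.12), ribosomal (0.0566, 0.0885, 0.0192 and 0.0493) and histone genes (0.0524, 0.0797, 0.0626 and 0.00318) in ENCORE samples, after quantile normalization within kits, without the narrow array and with that covariate. Without a call, scores turned for podocyte (0.0852) and ribosomal genes (0.0725) without the narrow array, ribosomal genes without that array and another (0.00468) and histone genes with the kit mean not removed (-0.0199). The cause of these turns and of the list calls lost or gained was not tested. Signal over background is unknown, so low values cannot be called absent.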

Other observations

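The tests in this part on the interferon contrast and without the narrow array were chosen after the results had been seen. Interferon gamma induced genes stood higher relative to type I interferon stimulated genes in AR biopsies. The difference between the 2 list scores was 0.52 ± 0.66 (SD, n = 15) in AR and -0.21 ± 0.56 (SD, n = 37) in non-AR, a gap of 0.74 (permutation p = 0.00011), and 12 of 15 AR biopsies exceeded the non-AR median. Without the narrow array the gap was 0.76 (permutation p = 0.00027).

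Macrophage and matrix scores moved together across biopsies, although the matrix score did not pass the test between groups. Pearson's r was 0.61 (permutation p = 1e-05, the smallest possible, adjusted p = 8e-05) and Spearman's rho 0.69 (permutation p = 1e-05, adjusted p = 8e-05), and r was 0.61 without the 2 samples farthest on the macrophage score. It was 0.68 in ENCORE and 0.59 in SPIA samples, and 0.68 in AR and 0.65 in non-AR biopsies. The T cell score had r = 0.27 with the matrix score (permutation p = 0.0516, adjusted p = 0.0688); the difference between these correlations was not tested.

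Lists of other classes gave few calls. Of 17 immediate early and stress genes FOS (0.38), KLF6 (0.41) and ZFP36 (0.35) rose, 5 adjusted over the list alone and 6 over all genes with the narrow array left out, KLF6 and ZFP36 not passing without a kit term (adjusted p = 0.0779 and 0.0853), and the score was higher by 0.47 (permutation test, adjusted p = 0.00629; list call adjusted p = 0.119 with an estimated correlation). Of 18 cell cycle genes BUB1 (0.24) and CCNA2 (0.31) rose, 3 adjusted over the list alone with MKI67 (0.32), which passed with the narrow array left out (adjusted p = 0.042; score difference 0.30, permutation test, adjusted p = 0.127; list call adjusted p = 0.386 with an estimated correlation). Of 7 mast cell markers SIGLEC6 (0.28) and CMA1 (0.45) rose, also adjusted over the list alone (score difference 0.28, permutation test, adjusted p = 0.0592). Of 18 histone genes H2BC14 rose (0.52) and H2BC5 fell (-0.63), each losing its call in other settings (H2BC14 at adjusted p = 0.0659 without a kit term, H2BC5 at 0.0775 with the narrow array left out and 0.0813 after quantile normalization within kits), and the score differed by 0.03 (permutation test, adjusted p = 0.891), or 0.16 with the narrow array left out (adjusted p = 0.428). No gene passed among 6 red blood cell and platelet, 12 skeletal muscle and adipose, 11 ribosomal protein and 10 housekeeping genes (limma over all genes), and adjusted over the list alone PPBP, a platelet gene, fell (-0.74), with score differences of -0.28, 0.27, -0.03 and -0.27 (permutation tests, adjusted p = 0.0592, 0.352, 0.891 and 0.233). With the narrow array left out, muscle, ribosomal and housekeeping score differences were 0.17, 0.07 and -0.08 (adjusted p = 0.551, 0.682 and 0.622). The muscle list went opposite ways in the kits by camera, lower in ENCORE (median -0.86, adjusted p = 0.00667) and higher in SPIA samples (median 1.64, adjusted p = 5.03e-06, 8 of 12 genes rising adjusted over the list alone, TNNC2 by 2.22). With an estimated correlation neither passed (adjusted p = 0.372 and 0.260). The muscle score differed by -0.33 in ENCORE and 0.81 in SPIA samples (exact tests, adjusted p = 0.445 and 0.0753), and the test of the difference between kits gave an adjusted p of 0.342 by permutation. The red blood cell and platelet score passed with the narrow array left out (adjusted p = 0.0445) and with the kit mean not removed (0.038), and lay between 0.0592 and 0.242 otherwise. For ribosomal protein and histone genes the median differences (-0.04 and -0.01) and the mean differences (0.01 for each) had opposite signs.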
